A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

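Chromatin immunoprecipitation followed by hybridisation to tiling arrays (ChIP-on-chip) was analysed for 2 samples of the fission yeast Schizosaccharomyces pombe. In the first, DNA recovered with an antibody against histone H4 acetylated at lysine 16 (H4K16ac) came from wild-type cells. In the second, DNA recovered with a Flag antibody came from cells that express Flag-tagged Bdf2. The strain differed between the samples, per the labels. Cells were grown at 30 °C and fixed with 3% paraformaldehyde for 30 min, per the labels. Each sample was hybridised to 1 array with 2 dyes, whole-cell extract DNA (input) in Cy3 and ChIP DNA in Cy5, so that positive values stand for ChIP above input. No dye swap, untagged strain, mock precipitation or total histone H4 array was analysed here, and each group held 1 array, so that array, strain and target cannot be separated and the shared slide cannot be examined as a batch.

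The deposited scanner files hold spot intensity values. Background subtraction, removal of spatial trends and dye normalization were done with Agilent Feature Extraction 10.7.3.1, per the file headers. The submitters' processing notes name Agilent Feature Extraction 8.5.1.1, and that difference was not resolved. The dye normalization was linear. Once the multiplicative spatial trend was put back, processed over background-subtracted intensity was a single factor per channel, and 100.0% of probes lay within 0.01 log2 of it on each array. The log10 ratio column in the deposited scanner files is the log10 of processed Cy5 over processed Cy3, and its error column is that of the scanner software. The series table holds ratio values made by the authors, with steps that are not given in the sources used here. On the log2 scale the deposited ratio followed ChIP over input with Pearson r = 0.999 for H4K16ac and 0.995 for Bdf2, and 98.8% and 98.7% of 42671 listed probes lay within 0.05 log2. The medians of the deposited ratio were 1.11 and 1.01, so that it was not centred.

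From the scanner files, log2(ChIP/input) was computed from the processed intensities. The 1227 control spots were left out, as were probes with a non-uniformity or population outlier mark in either channel, 16 for H4K16ac and 3 for Bdf2. Each array was centred on its median probe, with no loess or quantile step, since many probes of a ChIP array carry signal. The median shifted by the centring was 0.15 log2 for H4K16ac and 0.02 for Bdf2. Each remaining probe had 1 spot. Saturated spots were kept and give bounds, 17 in the ChIP channel for H4K16ac and 121 for Bdf2, of which 120 lie in pericentromeres.

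The probe design names an older genome build, so the 42695 probe sequences, with a median of 60 nt, were matched exactly to the ASM294v3 assembly. Of these, 42035 had 1 match, 658 had several and 2 had none, and 3 probes were mitochondrial. A probe with several matches was placed at each of them, and its value there is an average over the copies, weighted by their input. The median distance between neighbouring probes was 257 bp. Genes came from the RefSeq annotation of that assembly. The upstream value of a gene is the mean of probes centred within 500 bp upstream of the annotated gene start, and the coding value the mean of those in the coding sequence (for non-coding genes, in the gene).

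Pericentromeres were the longest interval of each chromosome without a protein-coding gene that held at least 3 tRNA genes. Subtelomeres were the outer 50 kb of each end of chromosomes I and II. Boundary elements were the outermost inverted repeats of each pericentromere, found with blastn 2.17.0 at 90% identity or more and 500 bp or more, and windows of 500 bp around pericentromeric tRNA genes. The mat2 gene is not named in this annotation, so the mating-type domain was left out, and the interval around mat3 was added after the data were seen. A Bdf2 run was at least 3 neighbouring probes at 2-fold or more, with gaps of at most 1000 bp.

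With 1 array per group there is no replicate error, so no test was made and no p-value is given. Intervals are 95%. Those of domains come from 1000 draws of 10-kb blocks of probes, those of genes from 1000 draws of genes, and those of shares of probes are exact binomial (Clopper-Pearson). They cover the spread between probes, genes or counts only, and the number of arrays limits the precision. Genes are not independent replicates. The spread between different probes placed within 30 bp of each other was 0.07 log2 (23 pairs), and the median error that the scanner software assigns to a spot was 0.21 log2 for both arrays.

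The lists of genes, the rule for named genes, the domain definitions and most alternatives were fixed before the data were examined. The 23 lists were ribosomal proteins, core histones, glycolysis, translation factors, chaperones and heat shock proteins, stress response, meiotic genes, heterochromatin island genes, nitrogen starvation, iron uptake, phosphate response, hexose transporters, Tf2 retrotransposons, wtf genes, subtelomeric helicases, mating-type cassettes, boundary and heterochromatin factors, cell cycle, cytoskeleton, tRNA genes, snRNA genes, snoRNA genes and other non-coding RNA genes. For each list, the percentile of its median among the medians of 10000 random lists of the same size, matched on deciles of input signal, describes these arrays and is no test. Random lists were drawn from protein-coding genes, or from all genes for the RNA gene lists. The symbols can1 and ydj1 were not found under their own names and were left out.

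Among protein-coding genes with at least 2 usable upstream probes, the genes named were the 10 highest and 5 lowest on each array and the 5 highest and 5 lowest in the difference between arrays scaled to unit SD. The rule also took the 2 highest and 2 lowest members of each list on each array, and always bdf2, epe1, swi6, clr4, act1, mei4, ssm4, tlh1 and tlh2, of which some have 1 upstream probe. The 5 strongest Bdf2 runs were named by genes that they overlap or lie near. The values of some genes that this rule takes are not reported here.

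The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with R 4.3.3 and limma 3.58.1 for the normexp and loess alternatives. The steps were tested on simulated data at the real probe positions with independent noise of each array's SD. With 200 genes raised by 1.0 log2 upstream, among 3369 genes with at least 2 upstream probes, the recovered median was 1.06 for H4K16ac and 0.98 for Bdf2. All 50 planted runs of 2.0 log2, which were longer than the run rule requires and lay at probes with 1 match, were recovered, with 0 others. Weaker or shorter runs and runs at shared probes were not tried. Of 200 lists of 15 genes without a shift, 3.5% fell outside the middle 95% of random lists on either array, against 99.5% for Bdf2 and 30.5% for H4K16ac with a shift of 0.3 log2. Means of independent noise spread less than single probes. Real upstream values had an SD over genes of 0.83 for H4K16ac and 0.31 for Bdf2, no smaller than that of probes. The rates with a shift may thus be too high for real lists. Alternatives covered the signal (normexp background correction with an offset of 50, background-subtracted signals without dye normalization, the deposited ratios), centring, bright probes, probes with 1 match, saturated spots, GC content, a loess on signal, thresholds, windows and domain widths.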

Results

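The 2 arrays measured a histone mark and a protein with domains that bind acetylated lysines in growing fission yeast. H4K16ac is acetylation of lysine 16 on histone H4, a mark of transcribed chromatin that is removed from silent chromatin. Bdf2 is a member of the BET family, proteins with a pair of bromodomains, and was precipitated through a Flag tag. There was 1 array for each target, with 42679 usable probes for H4K16ac and 42692 for Bdf2. The values are log2(ChIP/input) with the median probe of each array at 0, and positions are those of the ASM294v3 assembly. Both arrays had bright spots, and 99.995% of probes were well above background in both channels. The H4K16ac array had the wider spread, with an SD over probes of 0.81 against 0.28 for Bdf2. At 2-fold or more above the median probe lay 5348 H4K16ac probes (12.5%, interval 12.2 to 12.8) and 198 Bdf2 probes (0.464%, interval 0.402 to 0.533). The H4K16ac share became 22.1% and the Bdf2 share 2.72% with normexp background correction. Without replicate arrays no difference was tested.

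The first question was where H4K16ac lies relative to silent chromatin. H4K16ac was low over the pericentromeres and the subtelomeres, the repeat-rich domains that fission yeast packs into heterochromatin. The median of the pericentromeric probes lay 0.85 log2 below that of other probes (interval −0.94 to −0.80, 756 probes). The subtelomeres of chromosomes I and II lay 1.12 below (interval −1.20 to −0.99, 228 probes), and both kinds of domain together 0.92 below (interval −1.04 to −0.85). All 4 subtelomeres were similar, with medians of −1.11 and −1.15 at the left and right ends of chromosome I and −1.06 and −1.19 at those of chromosome II. The left end of I and the right end of II share most of their probes and are not separate measurements. There 19 of 47 and 8 of 37 probes had 1 match. Values were higher further from the ends of both chromosomes, with a difference from other probes of −1.25 within 10 kb, −0.86 between 50 and 75 kb and −0.04 between 100 and 150 kb. The outer 50 kb of the assembled chromosome III, which carries the ribosomal DNA at its ends, had medians of 0.00 on the left and −0.26 on the right. The subtelomeric helicase genes tlh1 and tlh2, which share their probes, read −1.17 upstream and −1.34 in the coding sequence. With a loess on signal the value over all silent domains was −0.63.

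H4K16ac medians were low at the outer repeats of all 3 pericentromeres, which share many of their probes. The 7 probes of the repeats of I that do not match those of II instead had a median of 0.70. They were split, with values up to 0.88 but also −0.46 and −0.55. The inverted repeats of pericentromere I (chromosome I, 3752588 to 3754866 and 3788242 to 3790520) had medians of −0.48 on both sides. Those of pericentromere III (chromosome III, 1069902 to 1075602 and 1135106 to 1140810) had medians of −0.73, and the longer repeats of pericentromere II, which are whole repeat arms rather than short boundary repeats (chromosome II, 1604848 to 1616570 and 1631312 to 1643033) had −0.84 and −0.85. Windows around tRNA genes had medians of −1.19 in pericentromere I, −1.03 in II and −0.68 in III, and the rest of the pericentromeres −1.01, −0.64 and −0.91. Taken as a set, boundary elements lay 0.83 below other probes (interval −0.94 to −0.78, 618 probes). That value was −0.55 with probes of 1 match, of which the set has 74, −0.41 with a loess on signal and −1.44 with normexp. Of those 74 probes 68 lie in the tRNA windows, so the value of −0.55 says little on the repeats.

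Median Bdf2 was above that of other probes over the pericentromeres and below it over the subtelomeres and the ends of chromosome III. The pericentromeric median lay 0.33 log2 above that of other probes (interval 0.28 to 0.43), and 56 pericentromeric probes reached 2-fold. The subtelomeric median lay 0.22 below (interval −0.31 to −0.02). The left subtelomere of chromosome II was lowest at −0.40, against −0.08 and −0.11 at the ends of chromosome I and −0.13 at the right end of chromosome II. Between 50 and 75 kb from the ends the median was −0.33, and over the outer 50 kb of chromosome III −0.28 and −0.19. Between 10 and 20 kb from the ends of I and II it was 0.14 (interval −0.83 to 0.89), and the left end of I had 3 probes at 2-fold or more. Over both kinds of domain the difference was 0.23 (interval 0.02 to 0.32), but it was −0.06 with probes of 1 match, 0.06 with a loess on signal and −0.08 with subtelomeres of 100 kb. Of the 327 probes with 1 match 200 are subtelomeric, against 229 of all 985, so that set weighs the 2 kinds of domain differently.

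The series title concerns the placing of Bdf2 at heterochromatin boundaries, and the highest Bdf2 probes of pericentromeres I and III lay in their outer repeats. The boundary set lay 0.35 above other probes (interval 0.30 to 0.48), the inverted repeats alone 0.29 (interval 0.25 to 0.36) and the tRNA windows alone 0.59 (interval 0.46 to 0.78). By repeat, the medians were 0.67 and 0.66 at pericentromere I, 0.52 and 0.50 at III, and 0.27 on both sides at II. The highest probes there reached 2.53 (5.79-fold), 2.03 (4.09-fold) and 1.14. The tRNA windows had medians of 0.45 in pericentromere I, 0.59 in II and 0.59 in III, and the pericentromeres outside boundary elements 0.17 (interval 0.04 to 0.46), with 0.06 in I, 0.11 in II and 0.34 in III, the last above the repeats of II. The boundary value was 0.53 with probes of 1 match and 0.12 with a loess on signal. Of the 74 boundary probes with 1 match 68 lie in the tRNA windows, so the value of 0.53 says little on the repeats. Of the 495 probes in the inverted repeats 6 had a single match, and 69 of the 76 probes of the repeats of I and 114 of the 171 of III also match those of II, so neither the 2 sides nor the chromosomes are separate measurements, and 116 of the 121 saturated Bdf2 spots had several matches, which makes their values lower bounds.

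**Figure D1:**
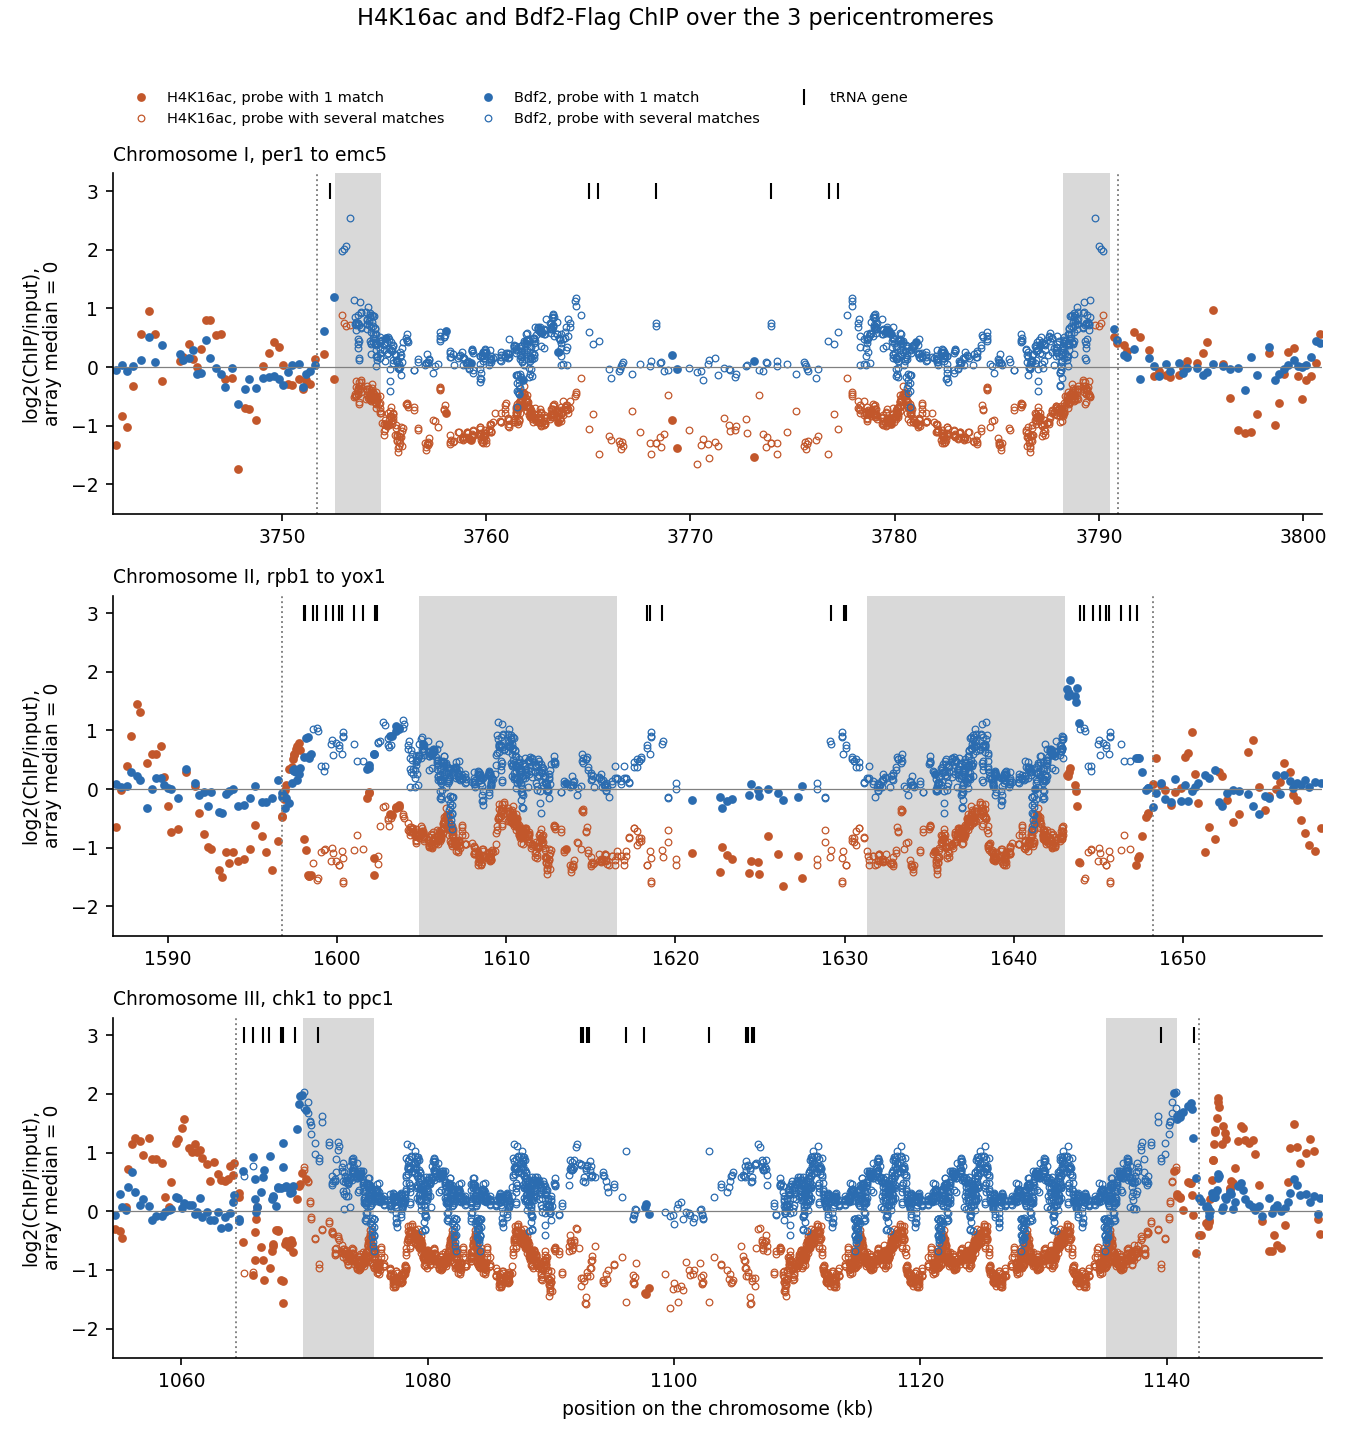
Probe values of both arrays over each pericentromere with 10 kb of flank, as log2(ChIP/input) with the array median at 0 against position in kb (filled points, probes with 1 match; open points, several; grey boxes, outermost inverted repeats; ticks, tRNA genes; dotted lines, flanking genes). H4K16ac lies mostly below 0 inside all 3 intervals, and Bdf2 reaches 2.53 at the outer edges of the repeats of chromosome I and 2.03 at those of III.

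Bdf2 formed 16 runs of at least 3 neighbouring probes at 2-fold or more, and 12 of them lay in the pericentromeres, where probes lie closer together and are placed at each copy of a repeat. Of the 16 runs 4 were under 100 bp. Because repeats share probes, the runs come down to 9 separate probe sets, 5 in pericentromeres and 4 elsewhere. The runs at the edge of heterochromatin were at chromosome I 3752513 to 3753577, near SPATRNAPHE.02 and per1, and 3789531 to 3790215, near emc5. They had means of 1.82 ± 0.54 (SD over 6 probes) and 1.95 ± 0.50 (SD over 5 probes). On chromosome III the runs covered 1069377 to 1070884 (mean 1.66 ± 0.27, SD over 14 probes) and 1139827 to 1142205 (mean 1.65 ± 0.23, SD over 20 probes), overlapping the non-coding RNA genes SPNCRNA.7183 and SPNCRNA.7235. On chromosome II a run that spans SPBTRNATYR.03, just outside the right repeat (1643127 to 1644167), had a mean of 1.48 ± 0.30 (SD over 10 probes). H4K16ac averaged 0.39, 0.51, 0.32 and 0.27 over the runs of chromosomes I and III just named, above the median probe, and −0.32 over that of chromosome II. The other pericentromeric runs were shorter, and H4K16ac averaged between −0.459 and −0.245 over each of them. H4K16ac was below 0 in 9 of 16 runs and, counted by probe set, in 4 of 9.

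The strongest run of all lay outside heterochromatin, at chromosome I 1216724 to 1217211, upstream of vip1, which encodes an RNA-binding protein. Its highest probe read 2.80 (6.94-fold) and lay 133 bp from the gene. The other runs outside pericentromeres were at chromosome III 1321050 to 1321490 across the start of the ribosomal protein gene rpl3402 (highest probe 2.22, inside the gene and 430 bp from vtc4), at chromosome I 3293377 to 3293892 at gde1 (2.18) and at chromosome II 730761 to 731233 at the start of the MAP kinase gene pmk1 (1.73). The number of runs depended on the rule, with 8 for probes of 1 match, 8 for the deposited ratios, 6 for at least 5 probes, 46 for at least 2 probes, 100 at 1.5-fold and 128 with normexp.

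At tRNA genes outside the pericentromeres Bdf2 was above and H4K16ac below the median probe. Over the 116 genes, with windows of 500 bp on either side, the median was 0.32 for Bdf2 (interval 0.28 to 0.33) and 113 genes were above 0. For H4K16ac it was −0.31 (interval −0.42 to −0.22), with 91 genes below 0. Other genes for small stable RNAs outside the pericentromeres were similar, with probe medians for Bdf2 of 0.49 at snRNA genes, 0.30 at snoRNA genes and 0.25 at rRNA genes, and for H4K16ac of −0.87, −0.49 and −0.40. At these tRNA genes on the Bdf2 array the input signal was 0.34 log2 below the median probe and the ChIP signal 0.01 below. The Bdf2 value was 0.17 with windows of 1000 bp, and the H4K16ac value moved between −0.52 with 250 bp, −0.16 with 1000 bp and −0.15 with a loess on signal.

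Around protein-coding genes both arrays peaked just inside the gene start. The mean was highest between 100 and 200 bp downstream of the start, at 0.65 ± 0.02 for H4K16ac and 0.20 ± 0.01 for Bdf2 (SE over probe and gene pairs). Between 900 and 1000 bp into the gene the H4K16ac mean was −0.10. Upstream values exceeded coding values for H4K16ac, with a median difference of 0.17 over 4895 genes (interval 0.15 to 0.20) and 58.3% of genes higher upstream. For Bdf2 the difference was −0.01 (interval −0.02 to −0.003), and it turned to 0.01 with a loess on signal and to 0.004 with windows of 250 bp. The H4K16ac difference was 0.31 with the loess and 0.09 with windows of 1000 bp. Upstream windows can hold parts of neighbouring genes, so the difference does not stand for intergenic against coding DNA. Over genes the H4K16ac medians were 0.38 upstream and 0.18 in coding sequence. Over single probes between divergent and between tandem genes they were 0.04 and 0.03.

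**Figure D2:**
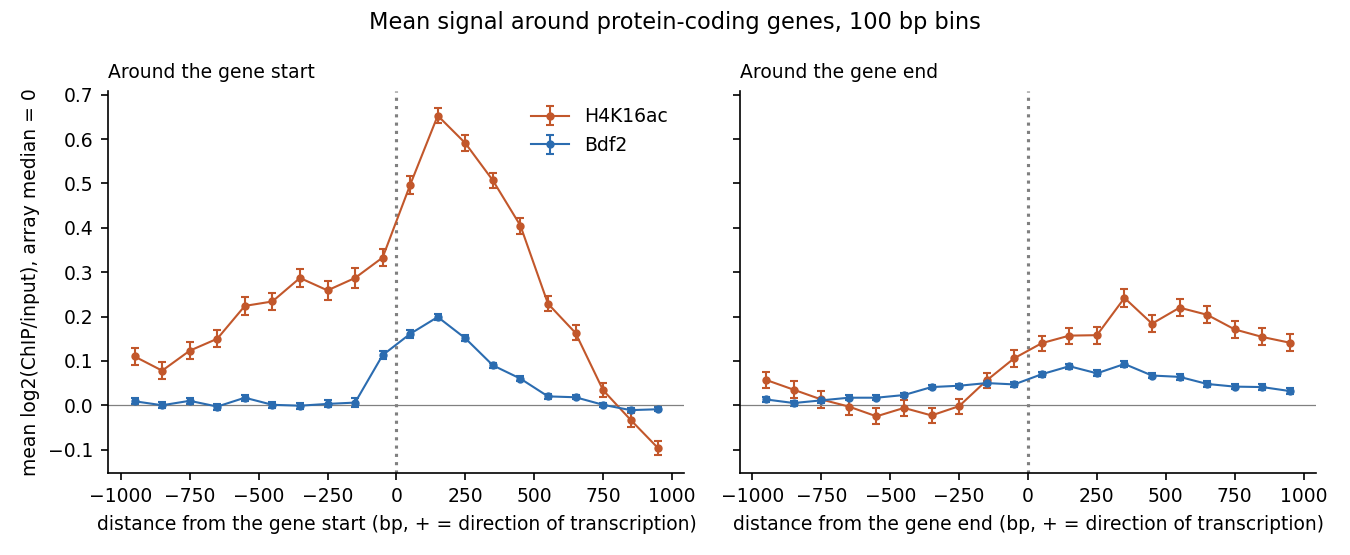
Mean log2(ChIP/input) of both arrays, with the array median at 0, in 100 bp bins around the annotated start and end of protein-coding genes, with the SE over probe and gene pairs. Both curves peak between 100 and 200 bp inside the gene, at 0.65 for H4K16ac and 0.20 for Bdf2.

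Among genes with at least 2 upstream probes, the 10 highest for H4K16ac were wbp4 at 2.18 ± 0.12 (SD over 2 probes), ism1, which encodes a mitochondrial isoleucine tRNA ligase, at 2.07, sif3 at 2.02, trm13, a tRNA methyltransferase gene, at 1.98, smc5 of the Smc5/6 complex at 1.96, mgs1 and the chromatin assembly factor gene pcf2, which share their upstream probes, at 1.95, SPBC1709.16C at 1.95, pop100 at 1.94 and sod22 at 1.93. The 5 lowest were tif51, the gene for the translation factor eIF5A, at −2.43 ± 0.10, pma1, the plasma membrane proton pump, at −2.32 ± 0.15, SPCC417.16 at −2.25 ± 0.77, scr1, a glucose repressor, at −2.25 ± 0.20 and exg1, a glucanase gene, at −2.24 ± 0.18. The actin gene act1 read 0.12 upstream and −1.38 in its coding sequence.

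Among the same genes, Bdf2 was highest upstream of vip1, at 2.35 ± 0.62 (SD over 2 probes). Next came vtc4 of the polyphosphate synthase complex at 1.56 ± 0.61, which shares upstream probes with rpl3402, SPAC2F3.18C at 1.51 ± 0.22, the RecQ helicase gene rqh1 at 1.49 ± 0.50, its divergent neighbour prh1, which shares its probes, at 1.40 ± 0.67, tho1 at 1.38 ± 0.34, rpl3402 at 1.23 ± 0.32, pmk1 at 1.21 ± 0.58, edc1 at 1.21 ± 0.21 and bdf1, the paralog of bdf2, at 1.13 ± 1.08. The lowest were the ammonium transporter gene amt1 at −1.31 ± 0.08, scr1 at −1.27 ± 0.66, the eisosome genes pil1 at −1.26 ± 0.12 and fhn1 at −1.22 ± 0.17, and tdh1, which encodes glyceraldehyde-3-phosphate dehydrogenase, at −1.19 ± 0.23. For the 250 genes lowest for Bdf2 the input signal on that array was 0.63 log2 above that of the median gene, and the ChIP signal 0.14 below. The genes were chosen by the ratio of these signals, so both values are partly set by the choice. On the H4K16ac array, which was not used to choose them, their input signal was 0.70 above.

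Among the genes always named, bdf2, epe1, swi6 and clr4 had upstream Bdf2 values between −0.13 and 0.27. The wider list of boundary and heterochromatin factors, given below, also held bdf1 at 1.13 and chp2 at −0.14. Upstream of bdf2 itself, with 1 probe, H4K16ac read −1.86 and Bdf2 0.27. For epe1, which encodes the JmjC-domain factor that counters heterochromatin, the values were 1.19 and 0.01, also from 1 probe. The HP1 gene swi6 read −0.45 and 0.21, and clr4, the H3K9 methyltransferase gene, −0.76 and −0.13 from 1 probe. At the heterochromatin island genes, mei4 read −0.42 for H4K16ac and 0.25 for Bdf2 upstream and ssm4 0.63 and −0.05, with Bdf2 coding values of 0.51 and 0.32.

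Across genes the arrays were related, and they shared more of their lowest than of their highest genes. Upstream values had a Spearman correlation of 0.456 (interval 0.430 to 0.482) and a Pearson correlation of 0.465 over 4993 genes, and coding values 0.228 and 0.214 over 4943 genes. These are correlations across genes of 1 array each. Of the 250 highest genes on each array 16 were shared, where independent lists would share 12.5. That count depended on the cut. With a loess on signal 10 were shared, but the top 10% by upstream value shared 97 genes and the top 5% by coding value 29. Independent lists would share 10% and 5% of each list, which is fewer in both cases. Of the 250 lowest 120 were shared, among them amt1, scr1, tdh1, pil1 and fhn1, which had H4K16ac values of −1.98, −2.25, −2.11, −2.10 and −2.03. The genes with the highest Bdf2 relative to H4K16ac were vip1, vtc4, rqh1, prh1 and ubi2, a ubiquitin fusion gene with −0.95 for H4K16ac and 1.07 for Bdf2. The lowest relative values were at SPAC18B11.09C (0.85 and −0.43), SPAC1399.01C (−1.08 and −1.17), ral2 (1.44 and −0.24), the septation scaffold gene sid4 (1.02 and −0.38) and mhf2 (1.63 and −0.15).

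**Figure D3:**
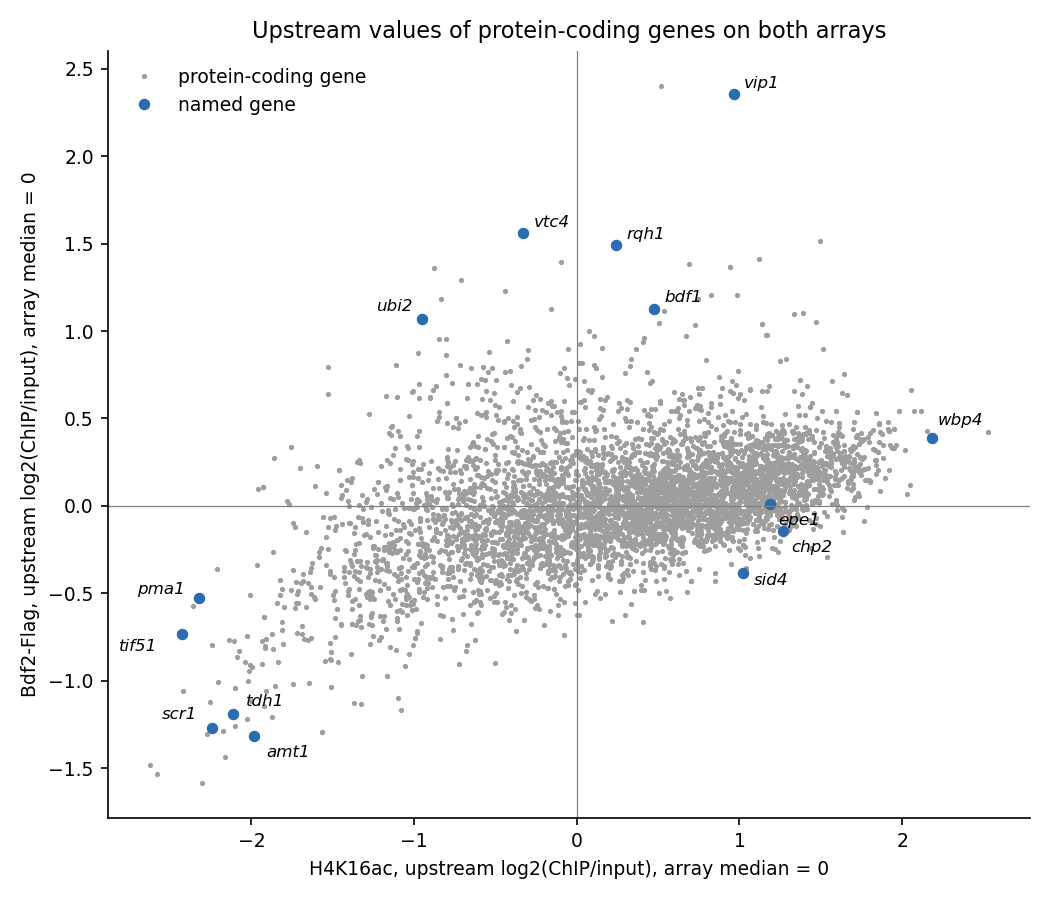
Upstream log2(ChIP/input) of protein-coding genes, H4K16ac on the horizontal and Bdf2 on the vertical axis, each with its array median at 0 and some named genes in blue. Genes low on both arrays form the lower left tail, with scr1 at −2.25 and −1.27, while vip1 is highest for Bdf2, at 2.35, among genes with at least 2 probes.

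Genes of the translation apparatus stood out on the Bdf2 array. The 131 ribosomal protein genes had an upstream Bdf2 median of 0.26, with 110 above 0, and a coding median of 0.40, with 113 of 115 above 0, both at percentile 100 of random lists. The random lists were not matched on gene length or on the distance of probes from the gene start, near which the Bdf2 mean was highest. Examples upstream were rpl3402 at 1.23 and rps901 at 0.96 against rpl3202 at −0.76 and rps802 at −0.22. Translation factors had 0.28 upstream (percentile 99.8) and 0.23 in coding sequence (99.5), from tif45 at 1.05 and tef101 at 0.45 to tif51 at −0.73, and the upstream median was 0.095 and inside the middle 95% with windows of 1000 bp. H4K16ac medians in coding sequence were −1.02 for translation factors (percentile 1.08) and −0.62 for ribosomal proteins, which is inside the middle 95% of random lists (13.6), as were −0.11 and −0.20 upstream (10.2 and 5.38).

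Genes for tRNA, snRNA and snoRNA were high for Bdf2 too. Over all nuclear tRNA genes, those of the pericentromeres included, the upstream Bdf2 median was 0.36, with 160 of 170 above 0. In the gene it was 0.73, with 52 of 52 above 0, but only 52 of 171 tRNA genes had a probe there. Among the tRNA genes that the naming rule takes, those with such a probe lay in pericentromeres and those outside had none. The value of 0.73 may thus not hold for tRNA genes in general. The snRNA genes had 0.41 upstream and, from 2 of 6 genes, 0.72 in the gene, and the snoRNA genes 0.22 and 0.43. These medians lay at percentiles 99.7 to 100 of random lists, but with windows of 1000 bp the upstream median of snRNA genes for Bdf2 came back inside the middle 95%. H4K16ac medians upstream were −0.54, −0.63 and −0.38 (percentiles 0, 5.27 and 0.06), of which that of snoRNA genes was −0.07 and inside the middle 95% with windows of 1000 bp, and in the gene −1.07, −1.02 and −0.85. Among tRNA genes, SPBTRNATYR.03 read 1.66 for Bdf2 and 0.03 for H4K16ac upstream, SPBTRNAALA.08 0.92 and −1.45, and SPATRNAASP.01 −0.48 and −1.44. The snoRNA gene snoU14 read 0.62 and −1.61. The large group of other non-coding RNA genes, with 6955 measured, had medians of 0.007 for Bdf2 and −0.08 for H4K16ac, both at percentile 0 of random lists. The middle 95% of random lists of that size was narrow, at 0.013 to 0.023 for Bdf2 and 0.018 to 0.051 for H4K16ac. These lists were drawn from a pool that consists largely of the same genes, so the Bdf2 percentile stands for a very small offset.

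Glycolysis, hexose transporter, nitrogen starvation, iron uptake and wtf genes were low upstream on both arrays. The 15 glycolysis genes had medians of −1.42 for H4K16ac, with 0 above 0, and −0.51 for Bdf2, with 1 above 0 (percentiles 0.05 and 0.155), the lowest for H4K16ac being tdh1 at −2.11 and gpm1 at −2.01. Hexose transporters had −1.24 and −0.42 (percentiles 0.04 and 0.135), with ght8 at −1.92 and −0.81. Nitrogen starvation genes had −1.52 and −0.39 (percentiles 0 and 0.28) and were split for H4K16ac, with 5 of 13 above 0, from amt1 at −1.98 and −1.31 to fnx1 at 0.83 and 0.09. Iron uptake genes had −0.88 and −0.45 (percentiles 0.25 and 0), with str3 at −1.71 and −0.55. In coding sequences the iron genes instead had a H4K16ac median of 0.48, at percentile 98.7, and a Bdf2 median of −0.08. Phosphate response genes had −0.38 and −0.31 (percentiles 15.8 and 2.44), with pho84 at −1.68 and −0.43, and wtf genes −0.99 and −0.42 (0.88 and 0.05), with wtf10 at −1.63 and −0.46. Some medians came back inside the middle 95% of random lists under another setting: with normexp those of nitrogen and hexose genes for Bdf2 and iron genes for H4K16ac, with windows of 250 bp that of glycolysis for Bdf2, and in 3 or more settings those of phosphate genes for Bdf2 and wtf genes for H4K16ac.

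Chaperone, stress, meiotic, histone and cell cycle genes were low upstream for H4K16ac. Chaperone and heat shock genes had an upstream median of −0.86 for H4K16ac (percentile 0.12) and −0.16 for Bdf2 (9.97), with hsp9 at −1.87 and −0.73 and mas5 at 0.74 and 0.29. Stress response genes had −0.80 (2.03) and −0.18 (14.5), with ctt1 at −1.33 and −1.13. Meiotic genes had −0.11 (0) and −0.06 (0) over 130 genes, with 58 and 55 of them above 0. Their H4K16ac median turned to 0.05 with a loess on signal. The 8 heterochromatin island genes had 0.07 (9.10) and 0.05 (47.3) upstream, and a Bdf2 coding median of 0.25 at percentile 99.9. Core histone genes had −1.03 (0.92) and 0.16 (97.2), with hhf2 at −1.41 and 0.15. Cell cycle genes had −0.54 (0.54) and 0.08 (76.3). The H4K16ac medians came back inside the middle 95% with normexp or windows of 250 bp for stress genes, a loess on signal for chaperones, windows of 250 bp for histones and of 1000 bp for cell cycle genes.

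The remaining lists were not set apart upstream. Boundary and heterochromatin factors had 0.87 for H4K16ac (percentile 96.3) and 0.02 for Bdf2 (33.8), with clr1 at 1.92 and 0.21, chp2 at 1.27 and −0.14 and bdf1 at 0.47 and 1.13. Cytoskeleton genes had 0.36 (33.1) and 0.17 (90.3), with nda3 at 0.55 and 0.36. The subtelomeric helicases had −1.17 (25.1) and 0.11 (85.4), and the 2 mating-type cassette genes that could be measured −0.45 (4.35) and −0.26 (4.30). The Tf2 retrotransposons had no measured member.

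**Figure D4:**
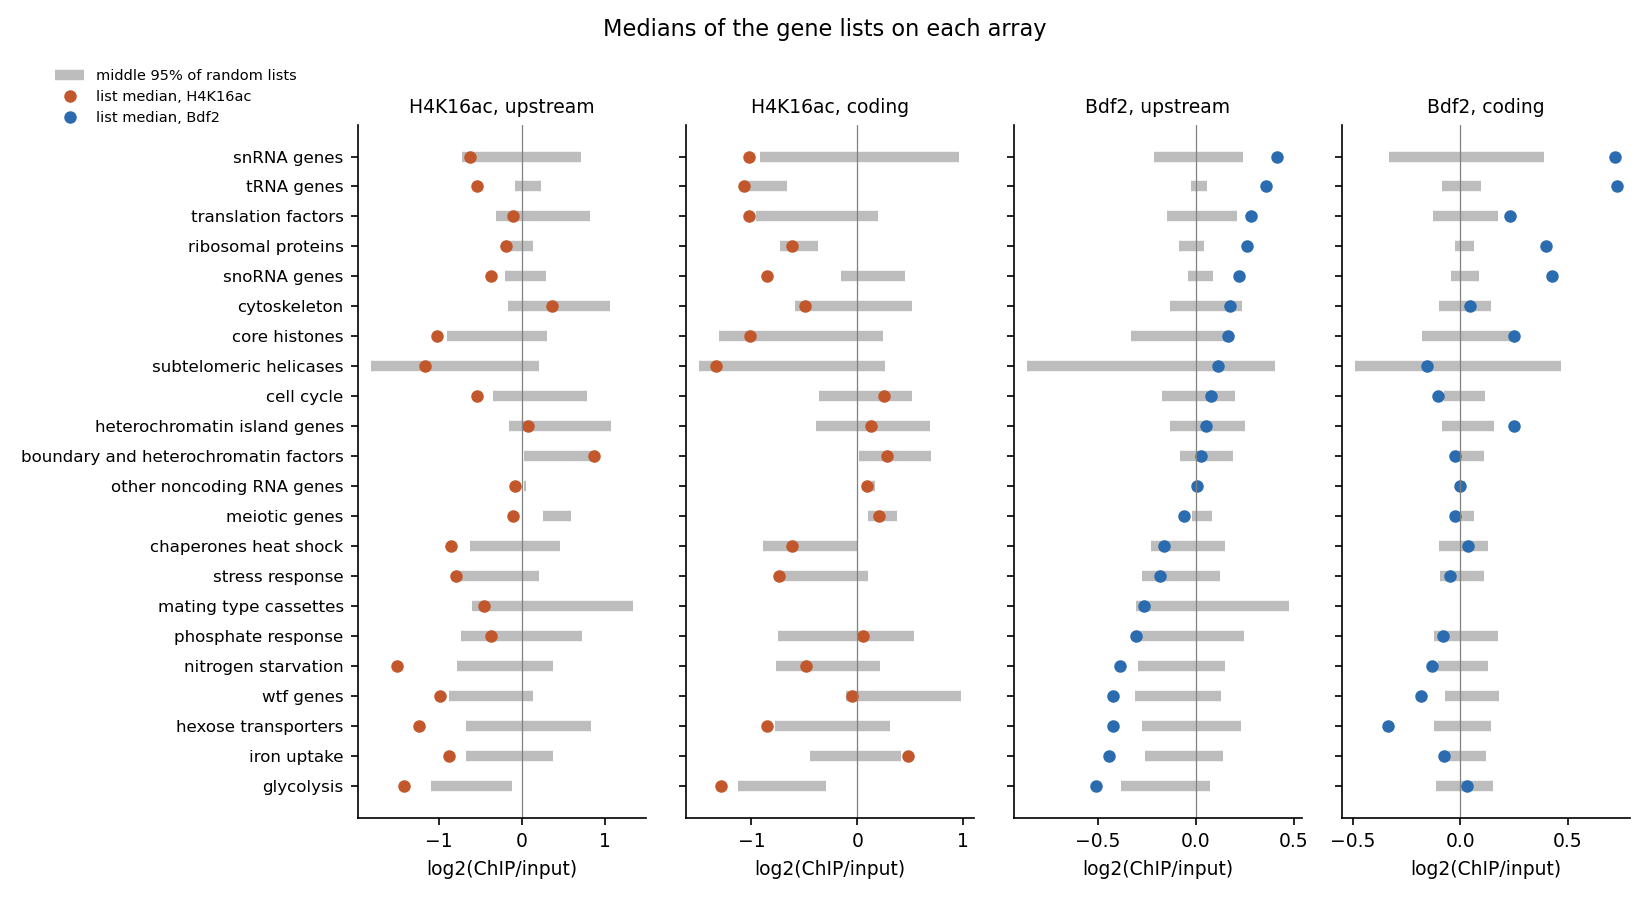
Median log2(ChIP/input) of each gene list (points) on each array, upstream and in the coding sequence or RNA gene, beside the middle 95% of the medians of 10000 random lists matched on input signal (grey bars), on axes that differ between panels. The tRNA, snRNA, snoRNA, ribosomal protein and translation factor lists lie to the right of the bars for Bdf2. The highest is 0.73, for the 52 of 171 tRNA genes with a probe in the gene. Upstream the lowest lists are nitrogen starvation for H4K16ac at −1.52 and glycolysis for Bdf2 at −0.51.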

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

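The tests of GC content, of input signal and transcribed genes at tRNA genes and of probes with several matches were chosen after the results they bear on were seen. The test of brightness at the inverted repeats was written down first, as was an earlier GC test there that left 0.529 with the GC trend removed but moved hardly any Bdf2 value, so that it decides nothing. In the main values of every result of this part the arrays lay on opposite sides, though not in every setting or subset given below. With 1 array each the difference was not tested.

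Values are Bdf2 minus H4K16ac in log2, not scaled to the spread of each array, which was wider for H4K16ac (SD 0.81 against 0.28). In the silent domains the difference was 1.16, at boundary elements 1.18 and at tRNA genes outside pericentromeres 0.63, each with H4K16ac below and Bdf2 above. Most probes of the boundary set match the repeat arms of chromosome II. The 7 probes of the repeats of I that do not match II had medians of 0.703 for H4K16ac and 1.97 for Bdf2. These 7 probes were split between high and lower values on both arrays, and some were negative for H4K16ac. In silent domains the Bdf2 side depended on the mix of domains, with 0.328 for pericentromeres alone and −0.217 for subtelomeres alone. It was −0.063 for probes of 1 match, of which 200 of 327 are subtelomeric, against 229 of 985 among all probes of these domains. For the tRNA list the difference was 0.90 upstream and 1.79 in the gene (52 of 171 genes), and for snoRNA genes 0.60 upstream and 1.28 in the gene. For snRNA genes it was 1.74 in the gene (2 of 6 genes) and for translation factors 1.26 in the coding sequence. It went the other way for upstream minus coding values, at −0.18 with Bdf2 itself at −0.012, and for the coding sequences of iron uptake genes, at −0.55 with Bdf2 at −0.076. The upstream minus coding value for Bdf2 was 0.011 with a loess on signal, so its sign is not stable.

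At the inverted repeats of pericentromeres I and III Bdf2 lay 0.53 above other probes (interval 0.43 to 0.88). Probes with several matches elsewhere in the pericentromeres, away from tRNA genes, lay at 0.19 (interval 0.15 to 0.27, 329 probes), which argues against shared probes as the whole cause, and probes of the same GC content outside tRNA windows and silent domains had a median of 0.032 (range over draws −0.00 to 0.07), which argues against GC content. A log ratio that follows spot brightness stays open. Removal of the signal trend left 0.29 with an interval from 0.17 to 0.67, too wide to decide, and these repeats are bright, with input 1.28 above the median probe on the Bdf2 array and 1.94 on the H4K16ac array. Binding of Bdf2 there is a biological explanation that 1 array without an untagged control cannot test.

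At tRNA genes outside the pericentromeres the Bdf2 median was 0.32, and probes of the same GC content elsewhere had −0.004 (range over draws −0.03 to 0.02), which argues against GC content. Less input DNA around these genes stays open, as do dimmer probes with a true ChIP gain, since the input signal lay at −0.335 relative to the median probe (interval −0.39 to −0.25) and the ChIP signal at −0.01. The list of all nuclear tRNA genes, those of the pericentromeres included, had an upstream Bdf2 median of 0.36. Random lists matched to it on input signal had medians of −0.03 to 0.06, so low input signal as such does not give the value of that list. No lists were matched to the genes outside the pericentromeres. Subtelomeres with input at −0.45 read −0.22 for Bdf2, and the H4K16ac array had input at −0.33 here with a ratio of −0.33. Those values decide nothing, since binding may differ there. Recovery of highly transcribed DNA whatever the tag cannot be told apart here. The glycolysis list, known for strong transcription, lay at percentile 54.8 of the Bdf2 coding values and the ribosomal protein list at 100.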

How the results depend on the processing

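No paired analysis was possible because each target had 1 array. Of 168 alternative values of the main results 114 stayed within the interval (for counts, within 1.5 times the value), 49 moved further and 5 turned sign. Of 3188 values of single lists and genes, 2758 stayed, 409 gene values moved by more than the SD between probes, 19 list medians came back inside the middle 95% of random lists and 2 turned sign. The cause of each change was not tested, unless fewer probes or other widths make it plain. Settings with 1 probe per 200 bp, single domains, single repeats and the mat3 interval were chosen after the data were seen. Spots were far above background, so dim probes set no limit.

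Normexp gave 22.1% of probes at 2-fold for H4K16ac and 2.72% for Bdf2, −1.25 for H4K16ac in silent domains, −1.44 and 0.486 at boundary elements, 0.381 for Bdf2 at tRNA genes, −0.034 for its upstream minus coding value, a correlation of 0.428 and 128 runs. A loess on signal gave 8.94% of H4K16ac probes at 2-fold, 0.313 for H4K16ac upstream minus coding and 0.011 for Bdf2 (turned), −0.631 in silent domains, −0.415 and 0.120 at boundary elements, −0.148 for H4K16ac at tRNA genes, 10 shared top genes, 10 runs and 0.053 for H4K16ac at meiotic genes (turned). Probes with 1 match gave 12.2% of H4K16ac probes, −0.553 and 0.531 at boundary elements, −0.063 for Bdf2 in silent domains (turned) and 8 runs. Of those probes 68 of 74 at boundary elements lie in tRNA windows, and 200 of 327 in silent domains are subtelomeric. The GC adjustment gave 0.132 for H4K16ac upstream minus coding and −0.744 at boundary elements. The deposited ratios gave 8 runs.

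At 1.5-fold 26.0% of H4K16ac and 2.43% of Bdf2 probes and 100 runs passed. Windows of 250 bp gave 0.197 and 0.004 (turned) for upstream minus coding, −0.516 and 0.447 at tRNA genes, a correlation of 0.423 and −0.001 for Bdf2 at other non-coding RNA genes (turned). Windows of 1000 bp gave 0.094 for H4K16ac upstream minus coding, −0.155 and 0.173 at tRNA genes and a correlation of 0.399. In silent domains Bdf2 was 0.322 with subtelomeres of 20 kb and −0.079 with 100 kb (turned). Pericentromeres alone gave −0.849 and 0.328, subtelomeres alone −1.12 and −0.217 (turned). At boundary elements, Bdf2 was 0.293 for inverted repeats alone and 0.589 for tRNA windows alone, and the repeats of I and III alone gave −0.647 and 0.526. Coding values gave a correlation of 0.228 and 29 shared top genes, and the top 10% shared 97. Runs numbered 46 at 2 probes, 6 at 5 probes and 9 with 1 probe per 200 bp.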

Other observations

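The test of input signal in the low upstream tail was written down before its result was seen, as was a removal of the GC trend that left 119 shared genes but moved hardly any Bdf2 value and so decides nothing. The GC test used here and the other values of this part were chosen after the data were seen.

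Intergenic regions outside silent domains differed by the direction of their neighbours. Between convergent genes H4K16ac had a median of −0.32 (interval −0.38 to −0.24, 618 probes), against 0.04 between divergent genes (interval −0.00 to 0.08, 3925 probes) and 0.03 between tandem genes (interval −0.01 to 0.06, 4072 probes). Bdf2 was instead highest between convergent genes, with 0.03 (interval −0.00 to 0.06), against −0.04 between tandem genes (interval −0.05 to −0.02) and −0.08 between divergent genes (interval −0.09 to −0.07). With the GC trend removed the convergent medians were −0.35 and 0.03 and the divergent ones 0.02 and −0.08.

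Long terminal repeats, the remnants of Tf retrotransposons, had a median of −0.83 for H4K16ac and −0.27 for Bdf2 over 95 probes outside the pericentromeres. The interval around mat3, the silent mating-type cassette between rpp202 and emc3 (chromosome II, 2128468 to 2138318), had −1.12 and −0.10 over 14 probes, with a highest Bdf2 probe of 0.23. Its flanking inverted repeats held 0 probes, so the boundaries of that domain were not measured. Within the pericentromeres probe values of the arrays were related, with a Spearman correlation of 0.388 over 756 probes and 0.327 over the 127 with 1 match, although H4K16ac was low and Bdf2 high as a whole.

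The 120 genes in the lowest 5% of both arrays upstream make a pattern that GC content does not account for, since other genes of the same upstream GC content had a Bdf2 median of 0.053 (range over draws −0.00 to 0.12). A candidate explanation is more input DNA at these regions. The 250 genes lowest for H4K16ac had an input signal 0.62 log2 above the median gene on the Bdf2 array (interval 0.51 to 0.69), an independent hybridisation. The Bdf2 ChIP signal of those 250 genes stood at 0.06, so low Bdf2 values there may reflect input more than loss of Bdf2. The 250 genes lowest for Bdf2 had an input signal 0.70 log2 above the median gene on the H4K16ac array. For the 120 shared genes the input on the Bdf2 array stood at 0.87 and the Bdf2 ChIP signal at 0.01, while H4K16ac ChIP stood at −1.05. The 120 genes were chosen by these same ratios, so their channel values are partly set by the choice and decide nothing. Brighter probes with fewer ChIP fragments would give the same ratio, and the biological explanation of few nucleosomes upstream of strongly transcribed genes was not tested, since no array of total histone was analysed here.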
